A study of Mus musculus with 6 samples.

How the data were processed

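The 6 samples are cortical neurons cultured from C57BL/6 mouse embryos at embryonic day 18, 3 labelled wild type and 3 labelled KDM6B knockout. Per the labels' protocols, cortices were kept separately, cells were dissociated with papain and plated in medium with horse serum, and that medium was replaced after some hours by a Neurobasal A medium with supplements. Total RNA was treated with DNase, and mRNA libraries were made with a KAPA HyperPrep kit, per the labels' protocols. How many days the cells were cultured, how many embryos went into a sample and whether replicates came from separate cultures are not given in the sources used here.

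The deposited values are in TPM, one column per library, although the name given to the table by the authors says FPKM: each column sums to 1000000. Per the submitters' processing notes, bcl2fastq 2.17, FastQC 0.11.2, TopHat, Picard 1.127, featureCounts and edgeR were used with the mouse build mm10, with no role or order stated. The gene annotation, the strand setting of the counting and the scaling step are not given in the sources used here. The design fixed before the data were examined assumed FPKM, and the same log-scale test was used for TPM. Because TPM divides by a library-wide total, a rise in a few abundant genes lowers all others, and because strand use is unknown, reads of overlapping antisense genes cannot be told apart. The table had 20040 entries, of which 671 were 0 in all libraries. It listed 27 names that a spreadsheet had turned into dates, which were kept but never named, and 2 repeated names. No other column of values was present.

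TPM keeps no depth by itself, but each value times the gene length fell on whole multiples of 1 step per library. The whole counts were recovered for all 19369 entries above 0, that is 100.0% of them, within a tolerance of 0.001 counts plus 2e-07 of the value. In simulated libraries 100.0% of 3852 genes came back exactly. The recovered totals lay between 22532813 and 26824482 counts per library, and 1 count was worth between 0.126 and 0.151 TPM for a gene of 1 kb. Recovered counts served to state the depth, to weigh low values and for 1 alternative test. Pairs of libraries within a group differed by more than counting noise: the median chi-square over genes was 1.41 to 2.30 times its expectation within groups and 3.08 to 4.20 times across groups. No library was therefore dropped as a copy of another. These values cannot tell separate cultures from repeat libraries of 1 culture.

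Genes with a mean of at least 0.5 TPM over the 6 libraries were tested, 14983 in all. KO was compared with WT by a linear model on log2 of TPM plus 0.5 with moderated variances that follow a mean trend (limma 3.58.1 in R 4.3.3), without covariates, and p-values were adjusted by the Benjamini-Hochberg method over all tested genes. Fold changes on this scale understate the change of genes with low values. The text gives the ratio of group means as fold or percent of WT. Gene lists and cell type marker lists were fixed before the data were examined and tested with limma's camera at a preset inter-gene correlation of 0.01, where at least 5 members were tested, with adjustment over the 23 lists that qualified. The text gives beside it camera with an estimated correlation for each list that passed. Fry, which tests a list without comparing it with other genes, was also run. All 26 mitochondrially encoded names were missing from the table, so that list is not analysed here. Symbols missing from the table were matched through RefSeq synonyms.

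Named genes were chosen by a rule fixed before the data were examined: Kdm6b, the 12 largest rises and 12 largest falls among genes that passed, with the 3 KO libraries on one side of the 3 WT libraries, a mean of at least 1 TPM and a name that is not a clone or predicted model, and in each list the 4 members with the smallest p that passed, or 2 members as values where none did. Some genes this rule picks are not reported here. As Y-linked genes and short-RNA loci filled part of that rule, it was applied a second time, after seeing the data, to autosomal genes with a locus of at least 200 nt. Positions come from GENCODE M21 on GRCm38, the same build as mm10, in which 94.6% of the gene names were found.

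The analysis was tested on simulated data with the means, lengths and depths of the real libraries, for the comparison of KO with WT over 14980 genes. Of 50 genes changed 1.2-fold, 20 were found, as were 40 of 50 at 1.5-fold, 43 of 50 at 2-fold and 46 of 48 at 4-fold. Of 160 calls 11 were false, which is 6.88%, and in a second run without any change 11 genes were called, all 11 with a mean of fewer than 20 counts, so calls on few counts are less certain. In the real data 40 of the 1632 calls were on so few. The simulation gave all genes the same overdispersion, 0.000249, and real genes that vary more are found less often. None of 20 lists of unchanged genes was called, and the list of moved genes was. Genes were simulated independently of each other, so this does not show how often lists of correlated genes are called wrongly.

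Alternatives planned before the data were examined were pseudocounts of 1 and 0.1, no filter and a filter at 2 TPM, median centring, quantile normalization, variances without a trend and with a robust trend, the replicate number as a block, leaving out each library in turn, and camera with an estimated correlation. After seeing the data, limma voom on the recovered counts, a run without loci under 200 nt and a run without genes on X and Y were added, as were 6 gene lists for the closing section: amino acid and tRNA-charging genes, actin-cytoskeleton genes with targets of SRF and YAP, and markers of thalamic, hippocampal, striatal and Cajal-Retzius neurons. The camera p-values of these 6 lists were adjusted over the 6 lists alone. Figures were drawn with matplotlib 3.10.9.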

Results

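mRNA from cultured cortical neurons of C57BL/6 mouse embryos at embryonic day 18 was sequenced in 6 libraries, 3 from wild-type (WT) embryos and 3 from embryos carrying a KDM6B knockout (KO). Kdm6b encodes a demethylase that removes repressive methyl groups from lysine 27 of histone H3, and the comparison asks which transcripts differ between the WT and KO neurons. Expression was given per gene as TPM, a length-scaled share of transcripts that sums to 1000000 per library, for 20040 gene entries. The whole counts behind these values added up to 24535584, 23639774 and 25848510 in WT replicates 1, 2 and 3, and to 24541143, 26824482 and 22532813 in KO replicates 1, 2 and 3. Correlations of log2 values lay between 0.987 and 0.988 within groups and between 0.983 and 0.984 across groups, over 14983 genes. WT replicate 3 had more of the ribosomal RNA precursor Rn45s, 6990 TPM where the other 5 libraries had 3750 to 4821 TPM. WT replicate 1 had the least of the RNA Bc1, 10789 TPM where the others had 13869 to 17977 TPM. The labels do not say that replicates came from separate cultures or litters, so p-values measure only the spread between these libraries, which may be technical.

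Kdm6b itself fell in each KO library. The gene spans 69398508 to 69413675 on chromosome 11 (GRCm38) and had 30.6 ± 0.279 TPM in WT (mean ± SD, n = 3) and 11.4 ± 0.536 TPM in KO (n = 3), which is 37.3% of the WT level. Single values were 30.9, 30.3 and 30.7 TPM in WT and 11.2, 11.1 and 12.0 TPM in KO, resting on 1392 to 1532 counts per WT library and 529 to 581 per KO library. Its log2 fold change was -1.39 ± 0.05 (SE; limma adjusted p = 1.1e-05). The value sums over the whole gene, and the labels do not say which part was deleted, so transcripts that lack the deleted part count as Kdm6b here. How much of the remaining signal in KO comes from intact transcripts cannot be told from these values.

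**Figure D1:**
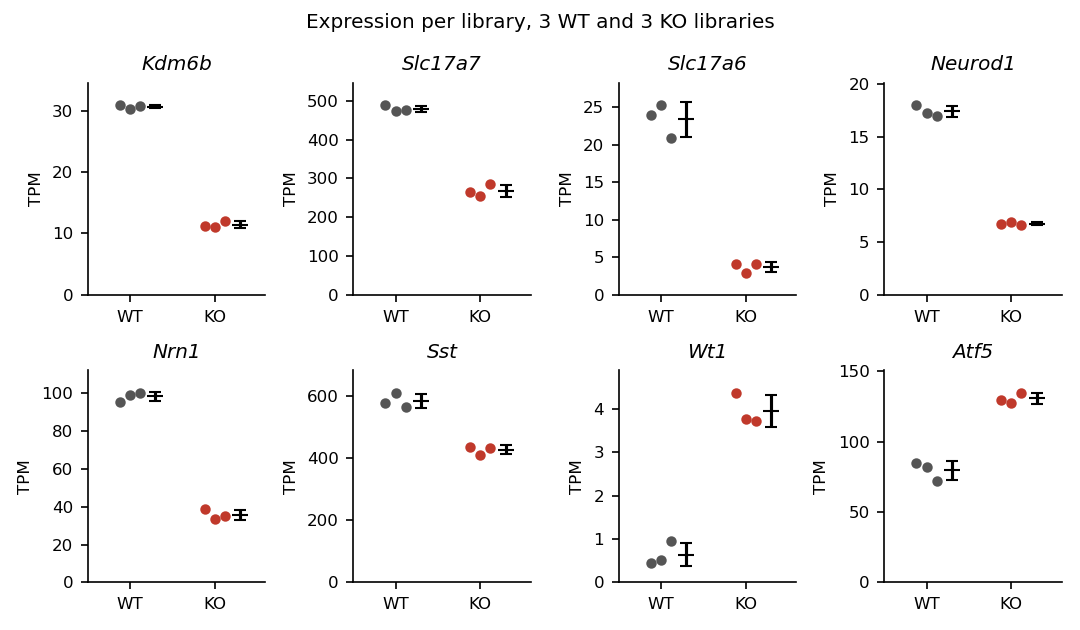
TPM of 8 genes in each library (points), with the mean and SD of the 3 WT and 3 KO libraries beside them; each vertical axis starts at 0. Kdm6b, the glutamate transporters Slc17a7 and Slc17a6, Neurod1, Nrn1 and Sst were lower in all 3 KO libraries than in any WT library, and Wt1 and Atf5 were higher.

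Of 14983 genes tested, 622 were higher and 1010 lower in KO at a Benjamini-Hochberg adjusted p below 0.05 (limma on log2 of TPM plus 0.5). Most differences were small. The median absolute log2 fold change among the 1632 genes was 0.26, 206 of them differed by at least 1.5-fold and 60 by at least 2-fold, of which 19 were higher and 41 lower. In all 1632 the 3 KO libraries lay on one side of the 3 WT libraries, which the test itself favours. So did 31.7% of all tested genes, where 10% would be reached if the libraries were interchangeable. Any difference between the groups, in genotype, sex mix or culture, can give such an excess. The balance of directions depended on scaling: 38.1% of the calls were higher in KO with TPM as deposited, 49.1% (792 higher and 820 lower) after median centring and 49.2% after quantile normalization. Leaving out 1 library lowered the counts by over 1.5-fold in 5 of the 6 cases, to 345 higher and 493 lower without WT replicate 1, 407 and 644 without WT replicate 2, 386 and 667 without KO replicate 1, 354 and 589 without KO replicate 2, and 365 and 589 without KO replicate 3. The counts were 406 and 658 without the variance trend, and 1083 and 1351 with limma voom on the recovered counts, an alternative chosen after seeing the data.

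The groups also differed in sex-linked transcripts. The Y-linked genes Eif2s3y, Ddx3y, Kdm5d and Uty held 43.7 ± 0.152, 26.1 ± 0.244, 14.2 ± 1.09 and 8.11 ± 0.656 TPM in WT (SD, n = 3) and between 0.361% and 0.548% of those levels in KO. Xist, the RNA that coats the inactive X chromosome of female cells, rose from 74.0 ± 3.49 to 231.5 ± 8.34 TPM (log2 fold change 1.64 ± 0.04 SE, adjusted p = 1.7e-06). The X-linked gene Kdm5c rose as well, 1.204-fold. Mid1, placed on X, and Erdr1, a gene of the region shared by X and Y, rose 2.36-fold and 2.60-fold. These rises were larger than those of the X-linked genes Eif2s3x, Kdm6a and Ddx3x, at 1.345-fold, 1.158-fold and 1.173-fold. A region shared by X and Y is present in both sexes, so the sex mix need not explain the rise of Erdr1. The cause of the Mid1 and Erdr1 rises was not tested. With the 499 tested genes placed on X and the 4 on Y left out, an alternative chosen after seeing the data, 595 genes were higher and 967 lower. Genes without a position here, Erdr1 among them, stayed in. Leaving these genes out cannot remove an effect of the sex mix on autosomal genes. Because Y-linked transcripts separate the groups completely, such an effect cannot be told apart from the genotype in any comparison given here.

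**Figure D2:**
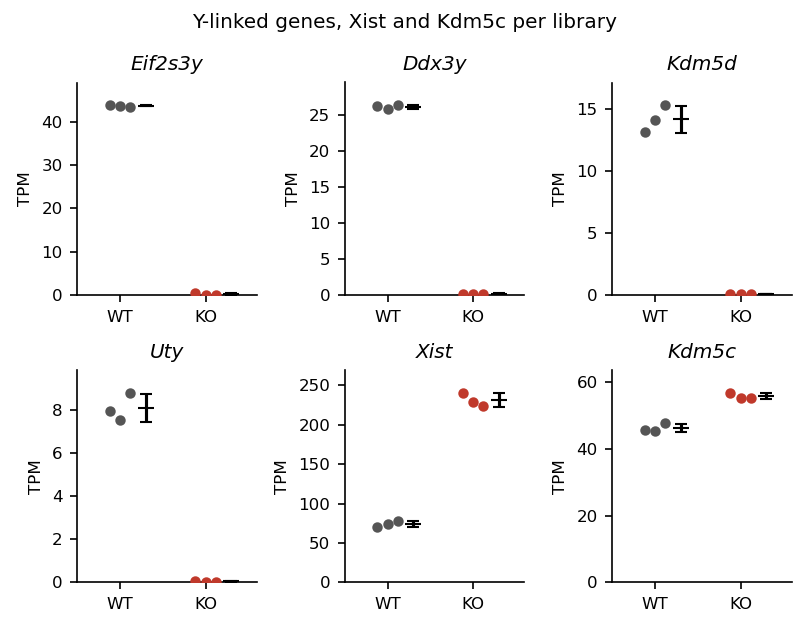
TPM of 4 Y-linked genes, Xist and the X-linked gene Kdm5c in each library (points), with group mean and SD (n = 3) beside them; each vertical axis starts at 0. The KO means of the Y-linked genes lay below 1% of their WT means, while mean Xist was 3.13-fold higher.

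Among autosomal genes with a locus of at least 200 nt, a restriction added after seeing the data, the largest rises were those of Wt1 and Fgd2. Wt1, which encodes a zinc finger transcription factor, rose from 0.639 ± 0.270 to 3.95 ± 0.367 TPM (43 counts over the WT libraries against 265 over KO; log2 fold change 1.99 ± 0.20 SE, adjusted p = 0.0011). Fgd2 rose 5.73-fold, and the homeobox gene Hmx1 2.75-fold. The neuropeptide gene Nts rose 2.44-fold, to 15.8 ± 0.520 TPM, and the protease gene Capn11 2.40-fold. Atf3, Spp1, Trib3, Klk8 and Plek2 rose by between 2.04-fold and 2.84-fold, but lost their calls in 2, 5, 3, 4 and 5 of the 6 fits that left out 1 library, at adjusted p up to 0.05375, 0.0983, 0.0628, 0.0814 and 0.1203. Trib3 and Plek2 also lost theirs without the variance trend (adjusted p = 0.053 and 0.053). The largest fall was that of Slc17a6, which encodes a vesicular glutamate transporter: it went from 23.3 ± 2.27 to 3.71 ± 0.650 TPM, 15.9% of WT (log2 fold change -2.51 ± 0.13 SE, adjusted p = 6.2e-05). Tac2, encoding a tachykinin peptide, fell to 18.7% of WT. Nrn1, which encodes the neurite growth protein neuritin, fell from 98.3 ± 2.46 to 35.8 ± 2.55 TPM, and Slc30a3, the zinc transporter of synaptic vesicles, from 21.7 ± 0.797 to 8.37 ± 0.706 TPM. Dlk1, Tfap2d, Slco1a4, Akr1c14, Anxa3 and Krt9 fell to between 31.9% and 38.9% of WT.

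Without that restriction, short-RNA loci filled part of both extremes. Of 566 tested loci under 200 nt, 31 passed the test, 25 of them on a mean of fewer than 20 counts per library. Mir675, AF357399 and Snora21 had 4, 1 and 0 counts over the 3 WT libraries and 35, 9 and 8 over the 3 KO libraries. Mir675 lies inside H19, which did not pass (151% of WT, adjusted p = 0.32), with 146, 105 and 55 counts in KO replicates 1, 2 and 3 and 60 to 75 in WT. Mir667, Mir7063, Mir7028, Mir744 and Mir300 had between 4 and 8 counts over WT and 0 over KO, while Mir431 had 16 against 2 and Snora34 17 against 2. Such loci often lie inside longer transcripts, so these reads need not come from the mature small RNA. AF357399 lost its call without WT replicate 1, WT replicate 3 or any single KO replicate (adjusted p up to 0.0623), and Mir431 without WT replicate 2 or WT replicate 3 (up to 0.0641). Both lost their calls without the variance trend (adjusted p = 0.061 and 0.064) and with a robust trend (0.055 and 0.082), and Mir431 at a pseudocount of 0.1 (0.057). Mir7028 and Mir300 missed the threshold with limma voom on the recovered counts (adjusted p = 0.099 and 0.094).

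Of 28 genes for postsynaptic scaffolds and signalling, 13 fell, 2 rose and 13 did not pass, and adjusted over the list alone 15 fell and 2 rose. Camk2a, a kinase of synaptic plasticity, fell from 496.6 ± 7.19 to 373.1 ± 5.20 TPM (log2 fold change -0.41 ± 0.02 SE), Baiap2 fell to 69.8% of WT and Nrgn to 81.4%. The list as a whole was lower than other genes (limma camera adjusted p = 6.6e-04, and adjusted p = 0.47 with an estimated correlation). Of 31 genes for presynaptic vesicle release, 10 fell and 2 rose, or 14 and 3 adjusted over the list alone. Slc17a7, the main vesicular glutamate transporter of cortical neurons, fell from 479.8 ± 7.62 to 268.6 ± 15.6 TPM, 56.0% of WT (log2 fold change -0.84 ± 0.04 SE, adjusted p = 5.3e-05), and the complexin gene Cplx2 fell to 80.6%. Syt4 rose 1.18-fold. The presynaptic list passed its test (camera adjusted p = 0.025, and adjusted p = 0.47 with an estimated correlation).

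Of 44 voltage-gated channel genes 13 fell and 4 rose, with 17 and 4 adjusted over the list alone (camera adjusted p = 8.1e-04, and adjusted p = 0.47 with an estimated correlation). Cacna2d1, an auxiliary calcium channel subunit, fell from 166.0 ± 4.34 to 108.3 ± 2.98 TPM and the potassium channel gene Kcnh1 to 64.6% of WT, while Scn3b and Kcnd2 rose 1.16-fold and 1.19-fold. Of 17 ionotropic glutamate receptor subunits 6 fell and none rose, or 9 and 0 adjusted over the list alone. Grin2a fell to 79.8% of WT, Gria1 to 84.8%, Gria3 to 87.5% and Grin1 to 88.1%. This list missed the threshold (camera adjusted p = 0.051, and adjusted p = 0.47 with an estimated correlation) but passed it at a pseudocount of 1 (0.047), without a filter (0.029), with a filter at 2 TPM (0.021), after median centring (0.041) or quantile normalization (0.029), with voom (0.0058) and without KO replicate 1 (0.042). The 12 GABA-A receptor subunits split, with 3 lower and 2 higher (4 and 2 adjusted over the list alone; camera adjusted p = 0.50): Gabrd fell to 67.2% of WT, and Gabrg1 and Gabra2 rose 1.40-fold and 1.125-fold.

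Of 20 genes for neuropeptides and granule proteins, 10 fell and 2 rose, or 12 and 5 adjusted over the list alone. Vip fell from 20.3 ± 1.75 to 9.53 ± 0.537 TPM (log2 fold change -1.05 ± 0.08 SE), and Tac2 is given above. Penk rose 1.43-fold beside Nts. The list did not pass its test (camera adjusted p = 0.051, and adjusted p = 0.58 with an estimated correlation), although it did at a pseudocount of 1 (0.047), without a filter (0.026), with a filter at 2 TPM (0.014), after median centring (0.029) or quantile normalization (0.013), with voom (0.0025), without loci under 200 nt (0.049) and without KO replicate 1 (0.017) or KO replicate 2 (0.049). Of 24 markers of GABAergic interneurons, 11 fell and 2 rose (13 and 3 adjusted over the list alone). The synthetic enzyme gene Gad1 fell from 305.6 ± 1.11 to 226.3 ± 12.4 TPM, Sst from 582.8 ± 23.4 to 425.5 ± 14.5 TPM and Nxph1 to 76.2% of WT. The interneuron list gave a camera adjusted p of 0.051 (adjusted p = 0.60 with an estimated correlation), and passed at a pseudocount of 1 (0.047), without a filter (0.039), after median centring (0.029) or quantile normalization (0.027), with voom (0.0012), without loci under 200 nt (0.049), without X and Y genes (0.037) and without WT replicate 2 (0.036) or KO replicate 1 (0.021).

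Genes of excitatory neuron identity went both ways, with 5 of 23 lower and 4 higher (9 and 8 adjusted over the list alone; camera adjusted p = 0.95). Neurod1, a transcription factor of neuronal differentiation, fell from 17.4 ± 0.513 to 6.76 ± 0.120 TPM (log2 fold change -1.30 ± 0.06 SE, adjusted p = 3.4e-05), and Neurod2 to 73.0% of WT. Fezf2 and Pou3f3 rose 1.28-fold and 1.24-fold. Of 41 axon guidance genes 9 rose and 3 fell, or 12 and 3 adjusted over the list alone (camera adjusted p = 0.013, and adjusted p = 0.47 with an estimated correlation). Ntng1 rose from 6.92 ± 0.203 to 14.0 ± 0.931 TPM, the ephrin receptors Epha7 and Epha5 rose 1.46-fold and 1.31-fold, and Slit3 fell to 65.6% of WT. Of 57 clustered protocadherins 3 passed, all higher, and none did adjusted over the list alone (camera adjusted p = 0.087, or 0.029 after median centring and 0.043 without KO replicate 2, and adjusted p = 0.60 with an estimated correlation). These were Pcdhb2, Pcdhb9 and Pcdhb10, at 1.24-fold to 1.25-fold, and each lost its call in 4 or 5 of the 6 fits that left out 1 library, at adjusted p up to 0.0782, 0.1038 and 0.1225. Pcdhb9 also lost its call without the variance trend (adjusted p = 0.070) and Pcdhb10 without a filter (0.073). Protocadherins of the alpha and gamma clusters share exons, so their values are uncertain.

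**Figure D3:**
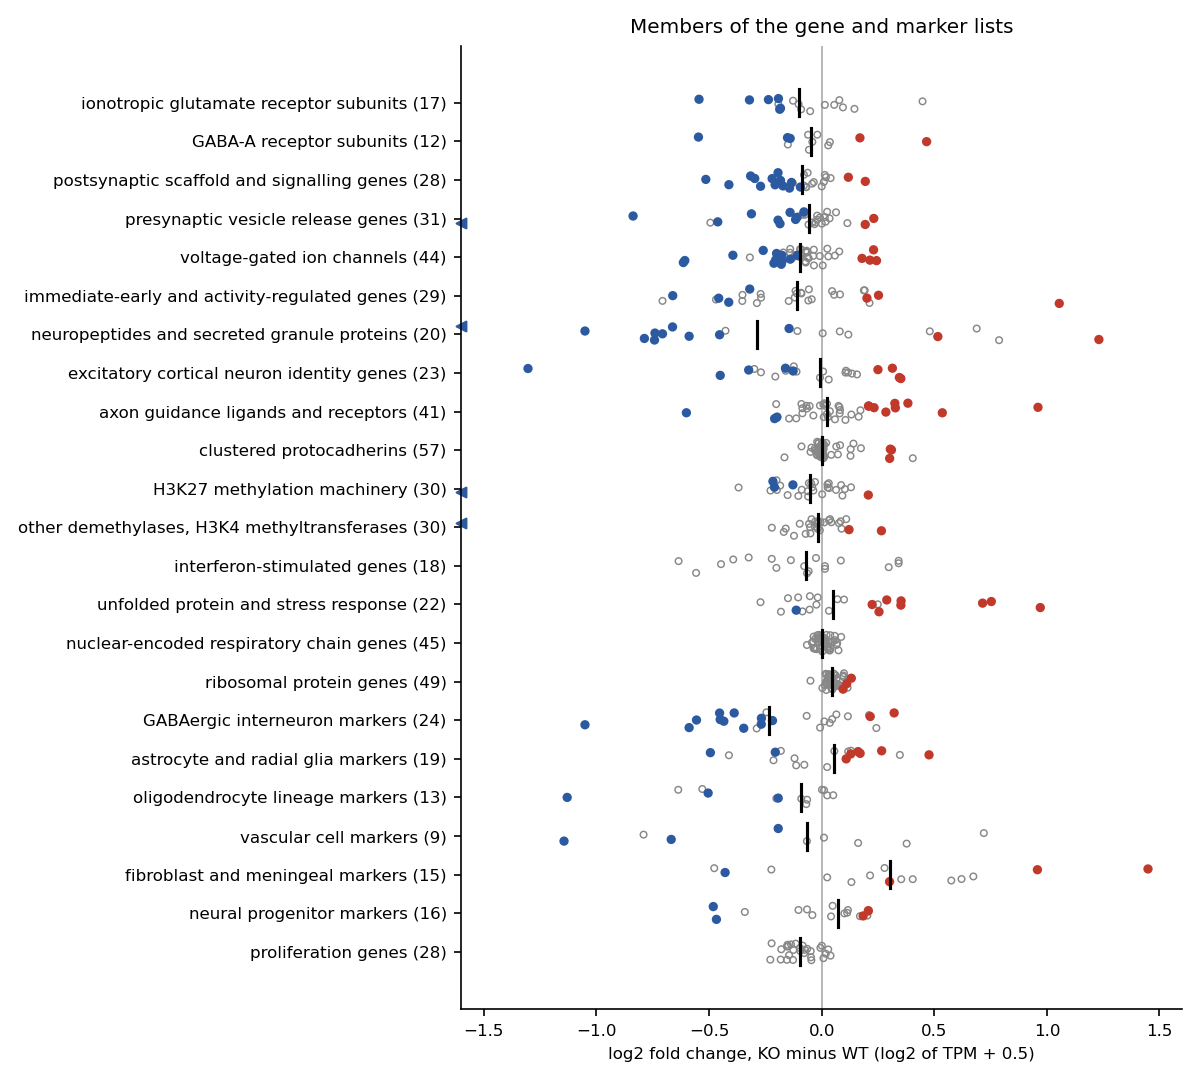
Log2 fold change (KO minus WT, log2 of TPM plus 0.5) of the members of 23 lists, with the number of tested members in brackets. Filled points passed the gene test (red higher, blue lower in KO), open points did not, black bars mark medians, and triangles at the left edge mark 4 values beyond the axis at -1.6. The median of the interneuron list lay at -0.23 and that of the fibroblast and meningeal list at 0.30.

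Of 22 genes of the unfolded protein and integrated stress responses 8 rose and 1 fell, or 10 and 4 adjusted over the list alone. Atf5, a transcription factor of that response, rose from 79.7 ± 6.69 to 130.8 ± 3.63 TPM (log2 fold change 0.71 ± 0.06 SE, adjusted p = 4.6e-04). The amino acid genes Phgdh and Psat1, which encode enzymes of serine synthesis, and Slc7a11, a cystine transporter gene, rose 1.28-fold, 1.17-fold and 1.28-fold. The list passed its test (camera adjusted p = 0.028) but not after quantile normalization (0.059) or with an estimated correlation (adjusted p = 0.47). Of 49 ribosomal protein genes 3 were higher, none adjusted over the list alone, a median log2 fold change of 0.05, a camera adjusted p of 1.4e-05 and an adjusted p of 0.50 with an estimated correlation. Rpl28 and Rplp0 were among them, at 1.07-fold and 1.10-fold. Rplp0 lost its call without any single library (adjusted p up to 0.1215) and Rpl28 without any but WT replicate 3 (up to 0.0853). Both lost them without the variance trend (adjusted p = 0.1253 and 0.1094), and Rplp0 without a filter (0.070). None of 45 nuclear-encoded respiratory chain genes passed with limma, also adjusted over the list alone, and none with voom, while 2 had an unadjusted p under 0.05 (camera adjusted p = 0.25), the 2 with the smallest p being Cox4i1 at 95.6% and Ndufa5 at 105.3% of WT. Cox4i1 passed after quantile normalization (adjusted p = 0.048). Nor did any of 18 interferon-stimulated genes, of which 4 had an unadjusted p under 0.05 and 1, Gbp2, passed with voom (adjusted p = 0.048; camera adjusted p = 0.33), of which Ifitm3 had 76.2% of the WT level (adjusted p = 0.057, or 0.043 with a filter at 2 TPM, 0.048 with a robust trend, 0.019 without loci under 200 nt and 0.0063 without KO replicate 2) and Gbp2 50.2%. Among 29 immediate-early and activity-regulated genes 4 fell and 3 rose, or 6 and 3 adjusted over the list alone (camera adjusted p = 0.44, or 0.035 without KO replicate 1, and adjusted p = 0.81 with an estimated correlation): Arc fell to 60.6% of WT, Rgs2 to 80.0% and Nptx2 to 71.9%, while Jun rose 1.15-fold. Nptx2 lost its call without WT replicate 1 (adjusted p = 0.053).

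Of 30 genes of the H3K27 methylation machinery 4 fell and 1 rose, or 7 and 1 adjusted over the list alone (camera adjusted p = 0.085, or 0.049 without a filter, and adjusted p = 0.50 with an estimated correlation). The Y-linked Uty was one of the 4. Cbx6 fell to 86.0% of WT and the X-linked Rbbp7 to 91.5%. Rbbp7 lost its call without WT replicate 1, WT replicate 2, KO replicate 1 or KO replicate 3 (adjusted p up to 0.0875) and without the variance trend (0.091). The 1 that rose was the X-linked Kdm6a, 1.16-fold. The calls of Uty and Kdm6a cannot be told apart from the different sex mix of the groups. Of 30 other histone demethylases and H3K4 methyltransferases only the Y-linked Kdm5d fell, and Kdm5c and Kdm4b rose, 1.204-fold and 1.09-fold, with the same counts adjusted over the list alone (camera adjusted p = 0.79). Kdm4b lost its call without any single library (adjusted p between 0.0615 and 0.1316), without a filter (0.056) or without the variance trend (0.1106).

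Markers of other cell types moved in different directions. Of 19 astrocyte and radial glia markers 6 rose and 2 fell, or 7 and 7 adjusted over the list alone (camera adjusted p = 0.24): Aldoc rose from 693.7 ± 16.5 to 965.5 ± 16.8 TPM and Ptprz1 1.203-fold, while Tnc and Aldh1l1 fell to 70.6% and 86.6% of WT. Of 15 fibroblast and meningeal markers 3 rose and 1 fell, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.0027, and adjusted p = 0.47 with an estimated correlation). Lum rose from 0.941 ± 0.0389 to 3.45 ± 0.476 TPM, Col1a1 2.13-fold (adjusted p = 0.014, or 0.051 without WT replicate 3) and Dcn 1.24-fold, with Col6a1 lower at 73.3% of WT. Dcn lost its call in 5 of the 6 fits that left out 1 library (adjusted p up to 0.118), without a filter (0.058) and without the variance trend (0.090), and Col6a1 without WT replicate 1 (0.0558). Of 13 oligodendrocyte lineage markers 3 fell and none rose, or 4 and 0 adjusted over the list alone (camera adjusted p = 0.085, or 0.022 without a filter, 0.016 with voom, 0.0076 without WT replicate 2 and 0.025 without KO replicate 3, and adjusted p = 0.61 with an estimated correlation), with Mal at 38.7% and Cspg4 at 87.3% of WT. Cspg4 lost its call without any single library (adjusted p up to 0.0872). Of 9 vascular markers 3 fell, or 4 adjusted over the list alone (camera adjusted p = 0.40), among them Kdr at 60.9% and Tagln at 45.4% of WT, the latter not passing without WT replicate 1 or WT replicate 3 (adjusted p up to 0.058), without the variance trend (0.058) or with a robust trend (0.078). Of 16 neural progenitor markers 2 fell and 2 rose, or 3 and 2 adjusted over the list alone (camera adjusted p = 0.40), with a median log2 fold change of 0.07 and a mean of -0.0066. Vim and Nes fell to 72.2% and 71.2% of WT. Dcx and Sox11, which young neurons also express, rose 1.14-fold and 1.16-fold. Dcx lost its call without WT replicate 1 (adjusted p = 0.055) or the variance trend (0.060) and Sox11 in 5 of the 6 fits that left out 1 library (up to 0.1413), without a filter (0.069) and without the variance trend (0.1137). None of 28 proliferation genes passed with limma, also adjusted over the list alone, and none with voom, while 4 had an unadjusted p under 0.05 (camera adjusted p = 0.051, or 0.047 at a pseudocount of 1, 0.026 without a filter, 0.042 after median centring, 0.049 without loci under 200 nt, 0.026 without KO replicate 1 and 0.0075 without KO replicate 2, and adjusted p = 0.60 with an estimated correlation). Bub1 had 84.2% and Ccnb1 90.8% of the WT level, and Bub1 passed with limma without the variance trend (adjusted p = 0.044). Only 3 of 17 microglia and macrophage markers reached the expression filter, and none of them passed with limma or voom or had an unadjusted p under 0.05. Aif1 stood at 138.6% of WT, on 11 counts over the WT libraries and 15 over KO. Its log2 fold change ran from -0.059 to 0.53 when 1 library was left out, so its direction is not settled. None of the 13 Hox genes in the table reached the filter.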

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

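The alternatives with voom, without loci under 200 nt and without X and Y genes were chosen after seeing the data, the others before. Kdm6b was lower and passed in each of them, with log2 fold changes between -1.42 and -1.35. The 622 higher and 1010 lower genes became 406 and 658 without the variance trend (the cause was not tested), 1083 and 1351 with voom on recovered counts (the cause was not tested), and 345 to 440 and 493 to 678 when 1 library was left out, where fewer samples remained. With the replicate block the counts were 360 higher and 585 lower and Kdm6b stayed at -1.39; the numbers do not pair the samples, since the deviations of same-numbered libraries correlated at 0.0077, -0.051 and 0.011 and 0 of 6 libraries correlated best with their own number. Of 23 lists 7 passed; 11 did at a pseudocount of 1, 13 without a filter, 12 after median centring, 11 with voom, 7 to 12 without 1 library and 0 with the correlation of members estimated instead of preset; the causes were not tested. Fry, which tests a list by itself, passed 14 lists, 6 of them among the 7. With the replicate block the presynaptic list missed the threshold (0.056), and the oligodendrocyte (0.022) and proliferation (0.042) lists passed it. Of 106 named genes that passed, 13 to 21 did not when 1 library was left out, 15 without the trend, 13 with the replicate block, 7 without a filter, 4 with a robust trend, 2 with voom and 1 at a pseudocount of 0.1. No named gene or list that passed turned its direction in any alternative. The tests planned for deposited whole-number counts were not run, since the table held TPM. Depth limits mainly short and weakly expressed loci, where 1 count is worth a large part of the value.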

Other observations

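The tests of this part and its gene groups, apart from the interneuron, activity-regulated, vascular and progenitor lists, were chosen only after the results were seen, so their counts are not independent evidence of a direction. Of 43 genes for amino acid transport, serine and one-carbon metabolism and tRNA charging, 19 were higher in KO and none was lower, with 24 not passing (limma camera adjusted p = 6.4e-15, and adjusted p = 0.23 with an estimated correlation). Pck2, a mitochondrial enzyme, rose from 9.99 ± 0.266 to 16.6 ± 0.954 TPM (SD, n = 3), the amino acid transporter gene Slc7a5 from 140.7 ± 13.2 to 210.2 ± 6.36 TPM, the translation repressor gene Eif4ebp1 from 18.0 ± 2.62 to 29.7 ± 1.46 TPM and Mthfd2, a mitochondrial folate enzyme, from 18.7 ± 1.31 to 26.0 ± 0.181 TPM. Many of these genes are known targets of ATF4, whose activity was not tested. Asns, a member of this group and of the stress response list, did not pass, at 107.1% of WT (limma adjusted p = 0.13). Phgdh, Psat1 and Slc7a11, among the 19 that were higher, are also members of both, so the results of this group and that list are not separate. Of the tRNA synthetase genes only Eprs passed, with a 1.09-fold rise.

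Of 40 actin-cytoskeleton genes and known targets of SRF or YAP, 15 were lower, 2 higher and 23 did not pass (camera adjusted p = 1.4e-05, and adjusted p = 0.23 with an estimated correlation). Of these, the actin-binding genes Actn1 and Flna and the YAP target Cyr61 were lower: Actn1 fell from 68.8 ± 2.19 to 47.9 ± 1.03 TPM, Flna from 76.2 ± 2.59 to 58.0 ± 2.62 TPM and Cyr61 from 36.8 ± 4.91 to 19.01 ± 1.52 TPM, while Actg1 and Csrp1 rose 1.10-fold and 1.15-fold. Among markers of other cells, the vascular markers Tagln and Kdr stood at 45.4% and 60.9% of WT and the progenitor markers Vim and Nes at 72.2% and 71.2%. Tagln and Vim are members of this group as well. Neither the vascular nor the progenitor list passed as a whole (camera adjusted p = 0.40 for each). Of 16 progenitor markers 2 fell and 2 rose, the latter being Dcx and Sox11, which young neurons also express. Tagln lost its call in some alternatives, as given above. At the imprinted region of chromosome 12 that holds Dlk1, at 31.9% of WT, the noncoding transcripts Meg3, Mirg and Rian stood at 74.6%, 76.9% and 93.4% of WT (adjusted p = 0.0022, 0.016 and 0.031). Within 10 Mb of Kdm6b on either side 25 of 295 tested genes passed, against 1471 of 13398 other autosomal genes (odds ratio 0.751, 95% interval 0.476 to 1.14, two-sided Fisher's exact test p = 0.19). Striatal projection neuron markers had 5 of 20 lower and 2 higher (camera adjusted p = 0.037, and adjusted p = 0.23 with an estimated correlation), with Tac1 and Ppp1r1b lower and Penk higher.

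The real split called 1632 genes and the other 9 splits of the 6 libraries at most 6, so 1 of 10 splits gave as many; 10 splits are too few for a share under 0.05.

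The sex-linked genes follow the groups: the KO means of the Y-linked genes were at most 0.548% of their WT means, and Xist in the single WT libraries was 30.6% to 33.6% of the KO mean. Of genes known to escape X inactivation (Eif2s3x, Kdm5c, Kdm6a and Ddx3x), 4 of 4 were higher in KO. This is what WT libraries that mix male and female cells and KO libraries with almost no male cells would give. It argues against a single embryo behind each WT library, since Xist was at least 30.6% of KO in each one that also held Y-linked transcripts; one common pool of WT embryos may be behind them, as the Y-linked genes varied by a median of 4.31% over the WT libraries, against 4.69% for 5265 autosomal genes of like expression, but pools with equal mixes would look the same, and the labels say that cortices were kept separately without saying when cells were combined. Whether the KO libraries, which all held almost no Y-linked transcripts, share an embryo or a pool cannot be told from these values. Genes on X and Y made up only 4.04% of the 1560 calls with a known position. Whether the different sex mix moved some of the 1497 autosomal calls cannot be told apart from the genotype, because the share of Y-linked transcripts separates the groups completely, and litter or culture differences stay open in the same way.

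Interneuron markers parted, with Dlx1 (43.1 ± 0.913 to 54.1 ± 2.44 TPM) and Reln (105.0 ± 0.538 to 122.0 ± 2.28 TPM) higher while Gad1, Sst and Vip were lower. The 24 markers differed by more than their errors (Cochran's Q = 939.7, 23 degrees of freedom), but this restates that they moved both ways and is no separate test of how many interneurons there were. Reln also marks Cajal-Retzius cells, so it need not follow interneuron number. A loss of interneurons, of all or some classes, together with an effect of the knockout on single genes may underlie this and stays open. Lower activity of the cultures may also lower peptide genes, but the activity-regulated list gave a camera adjusted p of 0.44 with members moving both ways, which decides nothing.

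The fall of Slc17a6 to 15.9% of WT could reflect a different share of a cell class that expresses it, such as thalamic, hippocampal or Cajal-Retzius neurons carried over in dissection. At or below the WT level of Slc17a6, 13 thalamic markers had a median log2 fold change of 0.19 (SD 0.48). The median was -0.25 (SD 0.27) for 9 hippocampal markers and -0.0193 (SD 0.33) for 8 Cajal-Retzius markers. As sets they did not fall as Slc17a6 did, at -2.51. But Slc17a6 was picked for its large fall, and on this scale weak markers such as Trp73, at 0.652 TPM in WT, cannot fall that far. The medians therefore do not decide whether fewer cells of these classes were present. Over all tested members, 4 of 17 thalamic markers were higher and 2 lower (camera adjusted p = 0.012), 1 of 22 hippocampal markers was higher and 6 lower (0.0075), and 3 of 13 Cajal-Retzius markers were higher and 2 lower (0.39), with an adjusted p of 0.23, 0.23 and 0.45 with an estimated correlation; the most abundant were Calb2, Mpped1 and Spock1, at 102.5%, 106.3% and 88.0% of WT. These classes, others that use this transporter, the sex mix and the genotype itself stay open.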
